A study of Mus musculus with 6 samples.

How the data were processed

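Whole brains of E14.5 mouse embryos were profiled by RNA sequencing in 3 knockout and 3 wild-type libraries, grouped by their titles. The deposited counts are whole numbers of reads per gene symbol with no normalization, as the values show. STAR 2.5.2a, featureCounts and DESeq2 1.12.4 are named in the submitters' processing notes, which also list the builds mm10 and hg19 with no role for either. The strand setting, the annotation release and the treatment of reads shared between paralogs are not given in the sources used here, so genes with near-identical copies or antisense partners, including the globins and Ctla2a, are uncertain. The authors' table also holds, per the file headers, a mean of normalized values, a log2 fold change with its standard error, a Wald score, and a p-value with its adjusted form. The 37 mitochondrially encoded genes were listed at 0 in each library, and their list was not tested.

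From the counts, genes were kept by filterByExpr in edgeR 4.0.16, which left 19565, and scaled by TMM. They were tested with the robust quasi-likelihood test, knockout against wild-type, with Benjamini-Hochberg adjustment at an FDR of 0.05. CPM values use the TMM-scaled library sizes. Of 52459 symbols, 48305 were matched to GENCODE M21 on GRCm38, 197 of them through a RefSeq synonym, for coordinates. Before the data were examined, 33 gene lists were fixed, and 32 could be tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2. Camera with an estimated correlation and fry were alternatives.

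The naming rule was also fixed then. It takes the target, the 10 highest and 10 lowest changes among genes past the threshold with at least 1 CPM in the higher group, no overlap between groups and a symbol that is not a clone or predicted-gene name, the 5 lowest p-values among such genes, and the 4 members of each list with the lowest p-value. Only 7 genes were lower, so all 7 are named.

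On simulated counts for 3 against 3 libraries and 19277 genes, the edgeR test recovered 68% of 50 genes changed 1.5-fold, 82% at 2-fold, 100% at 4-fold and 84% at 0.5-fold. Of its calls 4.02% were false, and 0 of 200 unchanged lists passed. The simulated genes varied independently of each other, and the changed ones had a mean of at least 1 CPM. The simulation therefore does not test lists of correlated genes, or calls where samples differ in ways other than genotype. Libraries held 43784619 to 50549673 counts, and the common biological coefficient of variation between samples was 15.3%. Counting error is small against that spread for abundant genes. It is not for scarce ones, such as Clca2 and Grm6 with wild-type means of 0.165 and 0.0841 CPM. No pair of libraries agreed within sampling noise.

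The alternatives were DESeq2 size factors, upper-quartile factors, other filters on low counts, DESeq2 1.42.0, limma-voom, a replicate block, each library left out in turn, erythroid or mitochondrially encoded genes removed, a sex term, stricter thresholds, and other windows around the locus. Fits that leave out 2 libraries, or add a Krt5 covariate or a beta-globin term, were added after seeing the data. Computations ran in R 4.3.3.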

Results

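Bulk RNA sequencing was carried out on whole brains dissected from C57BL/6 mouse embryos at E14.5. The series held 6 libraries, 3 labelled knockout for Mfsd7c and 3 labelled wild-type. The deposited count table summed to 43784619, 50549673 and 48612185 counts in knockout replicates 1, 2 and 3, and to 44793306, 49435273 and 49396317 in wild-type replicates 1, 2 and 3. The design addressed which transcripts differ between brains of knockout and wild-type embryos. The labels call the samples embryos but do not state litters, so the p-values measure the spread between these 6 samples. Wild-type replicate 2 had 82198 Xist counts and 0 counts over the Y-linked genes. The other 5 libraries had 6 to 27 Xist counts and carried Y-linked counts.

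Mfsd7c, whose current symbol is Flvcr2 (ENSMUSG00000034258.4), lies on chromosome 12 from 85746539 to 85813585 in the GRCm38 annotation and encodes a membrane transporter of the major facilitator superfamily. It was lower in each library labelled knockout than in each labelled wild-type. Knockout replicates 1, 2 and 3 had 119, 129 and 130 counts, and the wild-type replicates had 206, 291 and 259. The means were 2.67 ± 0.113 CPM (SD, n = 3) in knockout and 5.20 ± 0.573 CPM (SD, n = 3) in wild-type brains. The log2 fold change was -0.96 (SE 0.147, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0271). The remaining counts cannot be placed within the gene, because the table gives 1 count per gene and the deleted part is not given in the sources used here. The adjusted p was 0.121 without knockout replicate 1, 0.109 without knockout replicate 2 and 0.189 without knockout replicate 3. It was 0.184 without wild-type replicate 2 and 0.149 without wild-type replicate 3.

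In the knockout brains, 17 of 38 hypoxia response genes, 14 of 24 glycolysis genes and 8 of 27 endothelial tip cell genes rose in the edgeR test. The camera calls of these 3 lists were lost when the correlation was estimated (adjusted p = 0.202, 0.202 and 0.153 with an estimated correlation). Fry, the other alternative, called all 3 (fry adjusted p = 0.0192, 0.0192 and 0.0118). The 7 genes that fell were Slc38a5, Rgs5, Mmp9, Mfsd7c, Sox18, Cldn5 and Rnf112. Of 19565 genes tested, 129 passed an FDR of 0.05 in the edgeR quasi-likelihood test, 122 higher and 7 lower in knockout. Of these, 71 differed by at least 2-fold. The 10 highest by the naming rule were Clca2, Grm6, Tnfrsf8, Kcne3, Trib3, Ctla2a, Slc16a3, Tfpi2, Stc2 and Hapln1, with log2 fold changes from 2.48 (Hapln1) to 3.94 (Clca2). Several were scarce in wild-type brains, such as Kcne3 at 0.343 ± 0.106 CPM (SD, n = 3) against 4.16 ± 1.75 CPM (SD, n = 3) in knockout. Slc16a3, a lactate exporter, was abundant in knockout at 44.4 ± 9.43 CPM (SD, n = 3) against 5.48 ± 1.16 CPM (SD, n = 3). The part of the naming rule for low p-values added Apln, Adgrl4, Cd34, Esm1 and Mmrn2, all higher in knockout and expressed in endothelium. Slc38a5 and Mmp9, which fell, had p-values in the same range and were named among the lowest changes. The 3 knockout values did not overlap the 3 wild-type values for any of the 129 genes. Over all tested genes 14.4% showed no overlap, against 10% by chance.

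The number of genes passing rested on which libraries were included. It was 51 without knockout replicate 1, 111 without knockout replicate 2 and 41 without knockout replicate 3. It was 388 without wild-type replicate 1, 36 without wild-type replicate 2 and 44 without wild-type replicate 3. The fold changes of the 129 genes, which were selected with all 6 libraries, stayed about as large, with median ratios to the full fit from 0.942 without knockout replicate 3 to 1.07 without knockout replicate 2. With a term for embryo sex the number of genes passing was 37. That term rests on wild-type replicate 2 alone, the 1 female library. The fit nearly repeats the 36 without that library and is not a separate check, here or in the list counts below. The split by direction moved as well, to 233 higher and 155 lower without wild-type replicate 1 and to 251 higher and 58 lower in the DESeq2 Wald test.

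**Figure D1:**
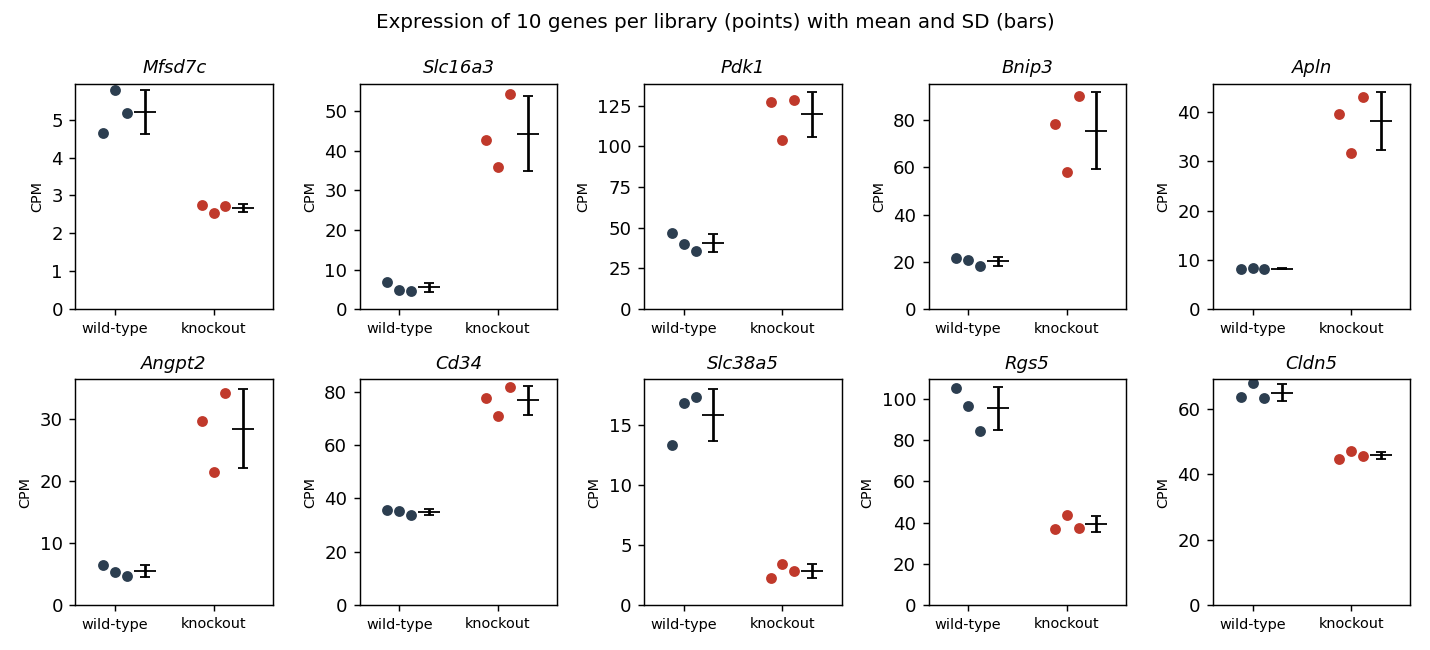
Expression in CPM, counts scaled to a common library size, of 10 genes in each of the 3 wild-type and 3 knockout libraries (points), with the group mean and SD (bars). Mfsd7c, Slc38a5, Rgs5 and Cldn5 are lower in all 3 knockout libraries, and the other 6 genes are higher in all 3.

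Genes induced by low oxygen rose in the knockout brains. Of the 38 measured members of the hypoxia response list, 17 rose, 0 fell and 21 did not pass the test over all genes. Adjusted over the list alone, 27 were higher and 1 was lower. The 17 became 9 without knockout replicate 1, 10 without knockout replicate 3, 5 without wild-type replicate 2, 6 without wild-type replicate 3, 5 with the sex term and 1 without both Hox-expressing libraries, wild-type replicates 2 and 3. Pdk1, a pyruvate dehydrogenase kinase, rose from 40.7 ± 5.56 to 120 ± 13.8 CPM (SD, n = 3), a log2 fold change of 1.56 (SE 0.115). Bnip3, a mitophagy receptor, rose with a log2 fold change of 1.90 (SE 0.156), and Ak4, an adenylate kinase, with 1.18 (SE 0.114). The list as a whole ranked above other genes with a median log2 fold change of 0.68 (camera in limma, preset correlation, adjusted p = 5.9e-25). That call was lost when the correlation was estimated from the 6 libraries (adjusted p = 0.202 with an estimated correlation).

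Glycolytic genes rose with them. Of 24 measured members, 14 rose and 0 fell, and 17 were higher and 0 lower when adjusted over the list alone. Pgk1, which makes ATP in glycolysis, rose from 207 ± 9.19 to 442 ± 47.1 CPM (SD, n = 3), and Gpi1, the glucose phosphate isomerase, from 168 ± 2.23 to 369 ± 54.0 CPM (SD, n = 3). The median log2 fold change was 0.81 (camera, adjusted p = 1.6e-21; adjusted p = 0.202 with an estimated correlation). The list shared 4 members with the hypoxia list. The 14 became 9 without knockout replicate 1, 8 without knockout replicate 3, 7 without wild-type replicate 2, 9 without wild-type replicate 3, 8 with the sex term and 2 without wild-type replicates 2 and 3.

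Endothelial genes moved in both directions. Of 27 endothelial tip cell genes, which mark the leading cells of vascular sprouts, 8 rose and 0 fell, and 17 were higher and 1 lower when adjusted over the list alone. The 8 became 5 without knockout replicate 1 or 3, 4 without wild-type replicate 2 and 4 without wild-type replicate 3. They became 12 without wild-type replicate 1 and 4 with the sex term. With the replicate block 16 rose and 1 fell. In the DESeq2 Wald test 15 rose and 1 fell, as they did without both knockout replicate 1 and wild-type replicate 1. Apln, a peptide ligand made by tip cells, rose from 8.16 ± 0.0976 to 38.1 ± 5.81 CPM (SD, n = 3), and Angpt2, a ligand that destabilises vessels, from 5.47 ± 0.945 to 28.5 ± 6.43 CPM (SD, n = 3). Esm1 rose with a log2 fold change of 2.37 (SE 0.169). The tip cell list had a median log2 fold change of 0.50 (camera, adjusted p = 5.5e-18; adjusted p = 0.153 with an estimated correlation). Of 30 pan-endothelial genes, 10 rose and 1 fell, with Cd34 at 1.14 (SE 0.0695), Pecam1 at 1.00 (SE 0.0829), Mmrn2 at 1.55 (SE 0.114) and Flt1 at 1.22 (SE 0.109) on the log2 scale. Adjusted over the list alone, 11 were higher and 3 lower (camera, adjusted p = 2.1e-05; adjusted p = 0.401 with an estimated correlation). Over all genes, 4 rose and 0 fell without knockout replicate 1, knockout replicate 3, wild-type replicate 2 or wild-type replicate 3, and also with the sex term. Without knockout replicate 2, 8 rose and 0 fell, without wild-type replicate 1, 10 rose and 3 fell, and without wild-type replicates 2 and 3, 3 rose and 0 fell. Of 40 angiogenic signalling genes, 7 rose and 0 fell (camera, adjusted p = 5.7e-06; adjusted p = 0.153 with an estimated correlation). That list is not confined to endothelial genes, and Apln, Angpt2 and Flt1 on it are also on the lists above. The 7 became 4 without knockout replicate 1, wild-type replicate 2 or wild-type replicate 3 and with the sex term, and 2 without wild-type replicates 2 and 3. Plvap, a diaphragm protein of leaky endothelium, rose from 5.94 ± 0.648 to 12.2 ± 1.05 CPM (SD, n = 3). It was the single member of the 11-gene leaky endothelium list to pass, and that list did not pass (camera, adjusted p = 0.255).

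The blood-brain barrier list did not pass as a whole (camera, median log2 fold change -0.03, adjusted p = 0.470). Of its 30 members 0 rose and 2 fell over all genes, and 5 were higher and 7 lower when adjusted over the list alone. The 2 became 1 without knockout replicate 1, knockout replicate 3 or wild-type replicate 2, with the sex term, and without wild-type replicates 2 and 3, and 2 members rose without wild-type replicate 1. Slc38a5, an amino acid transporter of brain endothelium, fell from 15.9 ± 2.18 to 2.83 ± 0.571 CPM (SD, n = 3), a log2 fold change of -2.48 (SE 0.175, edgeR adjusted p = 0.000854). Cldn5, the main claudin of its tight junctions, fell with a log2 fold change of -0.50 (SE 0.0585). Slc2a1, the barrier glucose transporter, had a log2 fold change of 0.57 (SE 0.0996) and missed the threshold (edgeR adjusted p = 0.0524). It passed in the authors' deposited table (DESeq2 adjusted p = 4.6e-05). In the DESeq2 Wald test 3 members of the list rose and 3 fell, as they did without knockout replicate 1 and wild-type replicate 1.

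The other genes that fell were Rgs5 at -1.28 (SE 0.0984), Mmp9 at -1.18 (SE 0.0866), Sox18 at -0.78 (SE 0.107) and Rnf112 at -0.44 (SE 0.0712) on the log2 scale. Rgs5, a marker of pericytes, fell from 95.5 ± 10.6 to 39.3 ± 3.80 CPM (SD, n = 3). It was the 1 member of the 24-gene mural cell list to pass over all genes, and 6 members were lower and 0 higher when adjusted over the list alone. The number that fell became 2 without wild-type replicate 1, in the DESeq2 Wald test and with the replicate block, and 3 with the Krt5 covariate. Without both knockout replicate 1 and wild-type replicate 1, 2 fell and 1 rose. The mural list had a median log2 fold change of -0.20 (camera, adjusted p = 3.0e-04; adjusted p = 0.226 with an estimated correlation). Of 33 basement membrane and vascular matrix genes 4 rose and 0 fell, and 13 were higher and 0 lower when adjusted over the list alone. The 4 were the laminin chain gene Lama4 at 0.57 (SE 0.0635), the crosslinking enzyme Loxl2 at 1.35 (SE 0.164), and the collagen hydroxylases P4ha1 at 1.19 (SE 0.148) and Plod2 at 0.68 (SE 0.111). P4ha1 and Plod2 are also among the 4 members shared with the hypoxia list. The 4 that rose became 0 without wild-type replicate 2, 0 without wild-type replicate 3, 0 with the sex term and 0 without wild-type replicates 2 and 3. They became 2 without knockout replicate 1, 1 without knockout replicate 3 and 7 without wild-type replicate 1. The DESeq2 Wald test gave 10, the replicate block 12, and leaving out both knockout replicate 1 and wild-type replicate 1 gave 11. The list had a median log2 fold change of 0.26 (camera, adjusted p = 8.6e-09; adjusted p = 0.153 with an estimated correlation).

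**Figure D2:**
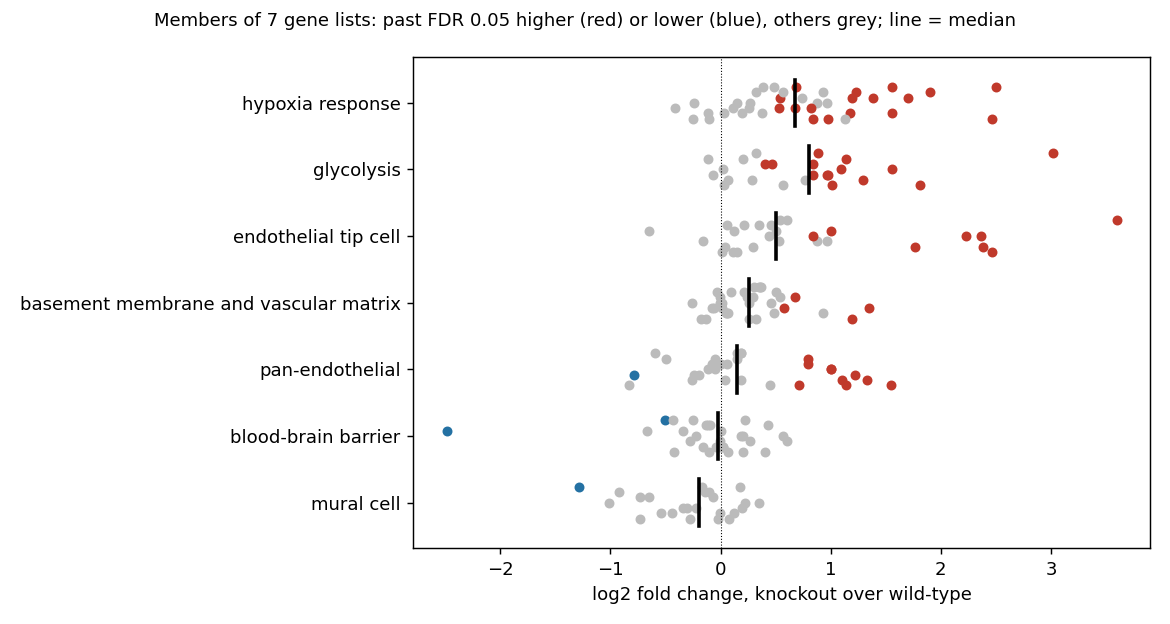
Log2 fold change, knockout over wild-type, of each measured member of 7 gene lists (points), with the list median (line). Red members rose and blue members fell at FDR 0.05. Hypoxia, glycolysis and tip cell members lie mostly right of 0, and blood-brain barrier members lie on both sides with a median of -0.03.

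Of 32 lists tested, 15 passed an FDR of 0.05 in camera, 12 higher and 3 lower. Markers of other cell types were among them. The microglia and macrophage list ranked higher with 0 of 31 members past the threshold (camera, adjusted p = 1.9e-05; adjusted p = 0.334 with an estimated correlation). The erythroid list ranked higher with 0 of 21 (camera, adjusted p = 6.2e-04; adjusted p = 0.392 with an estimated correlation). The interferon and inflammation list ranked higher with 1 of 21, H2-K1 (camera, adjusted p = 7.0e-06; adjusted p = 0.401 with an estimated correlation). The nuclear oxidative phosphorylation list ranked lower with 0 of 42 (camera, adjusted p = 7.2e-04; adjusted p = 0.754 with an estimated correlation). With an estimated correlation 0 of the 32 lists passed in camera, the lowest adjusted p being 0.153, 6 had an unadjusted p under 0.05, and fry called 6. The oxidative phosphorylation list, as mean log2 CPM relative to each gene's mean, was at 0.179 in wild-type replicate 1. It was at -0.00669 and -0.0548 in wild-type replicates 2 and 3, against -0.0200, -0.0589 and -0.0388 in knockout replicates 1, 2 and 3. The microglia, erythroid and interferon lists also overlapped between the groups, with knockout replicate 2 below wild-type replicate 1.

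The share of genes called near the targeted locus, leaving out the target, was compared with the share elsewhere. Within 10 Mb of Mfsd7c, 0 of 155 tested genes passed, against 127 of 18883 elsewhere (two-sided Fisher's exact test, p = 0.630). Of the 155, 5 had an unadjusted p under 0.05 in edgeR, DESeq2 called 1 and limma-voom called 0. Within 20 Mb edgeR called 2 of 293 genes (two-sided Fisher's exact test, p = 0.723), and within 2 Mb 0 of 72.

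In the authors' deposited table, 308 genes passed an adjusted p of 0.05, 250 higher and 58 lower in knockout. They included all 129 genes called by edgeR, each with the same sign. The authors' deposited table rests on the same 6 libraries, so this overlap is not independent evidence.

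The libraries also differed in Krt5 and embryonic beta-globins, which overlapped between the groups, and in Hoxb3, which did not. Krt5, an epidermal keratin, was at 105, 3.73 and 20.4 CPM in knockout replicates 1, 2 and 3, and at 79.9, 3.54 and 0.339 CPM in wild-type replicates 1, 2 and 3. Hoxb3, a hindbrain and spinal cord gene, was at 14.3 CPM in wild-type replicate 2 and 6.28 CPM in wild-type replicate 3, and at most 0.676 CPM in the other libraries. Embryonic beta-globins made up 2.80%, 23.6% and 5.03% of beta-globin counts in knockout replicates 1, 2 and 3, and 4.49%, 23.3% and 26.5% in wild-type replicates 1, 2 and 3. The first principal component, with 50.2% of the variance, parted knockout replicates 1 and 3 and wild-type replicate 1 from the other 3 libraries. Grouping the libraries along that line called 1824 genes in edgeR, against 129 for genotype. In fits chosen after seeing these values, a term for the beta-globin sets gave 236 genes, and leaving out knockout replicate 1 and wild-type replicate 1 gave 459, of which 265 were higher and 194 lower. Leaving out wild-type replicates 2 and 3 gave 20.

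**Figure D3:**
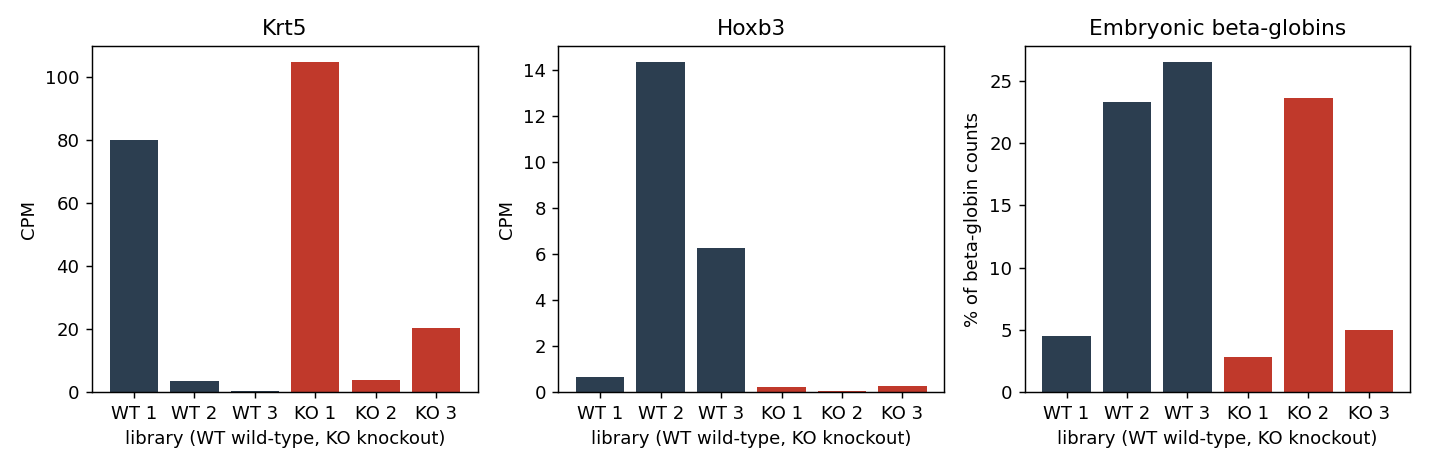
Krt5 and Hoxb3 in CPM, and embryonic beta-globins as a percent of beta-globin counts, for each library (bars; WT wild-type, KO knockout). Krt5 is highest in knockout replicate 1 and wild-type replicate 1, Hoxb3 in wild-type replicates 2 and 3, and the globin share lies above 20% in 3 libraries of both groups.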

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

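The fits without the epidermal or Hox-expressing libraries and those with a Krt5 covariate or beta-globin term were chosen after seeing the data. Counts below are all genes past the threshold, then higher and lower, against 129, 122 and 7. DESeq2 size factors gave 128 genes, upper-quartile factors 127 and limma-voom 118. No low-count filter gave 211, 190 and 21, and the DESeq2 Wald test 309, 251 and 58. With a sex term, which rests on 1 female library, they were 37, 34 and 3. An FDR of 0.01 gave 49, 45 and 4, and a 2-fold minimum 71, 68 and 3. Leaving out the epidermal libraries gave 459, 265 and 194, and leaving out the Hox-expressing libraries, with 1 wild-type library assumed to vary like the others, 20, 16 and 4. The Krt5 covariate gave 323, 254 and 69, and the beta-globin term 236, 205 and 31. Leaving out single libraries gave 36 to 388 genes, 33 to 233 higher and 3 to 155 lower. The causes were not tested.

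Whether replicate numbers pair the samples was not settled. Deviations correlated at 0.587, 0.310 and 0.034 for numbers 1, 2 and 3. Knockout replicate 2 correlated best with wild-type replicate 3 (0.478). The replicate block gave 282 genes, 212 higher and 70 lower.

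The log2 fold change of Mfsd7c was -1.03 to -0.88 without single libraries, where its call was lost in 5 of 6 fits. It was -0.88 with the sex term (adjusted p = 0.170) and -0.79 without the Hox-expressing libraries (adjusted p = 0.381). With an estimated correlation camera called 0 lists, with adjusted p = 0.202 for hypoxia response, 0.202 for glycolysis, 0.401 for pan-endothelial, 0.153 for endothelial tip cell and 0.153 for basement membrane and vascular matrix. Fry called 6 lists. Its adjusted p was 0.0192 for hypoxia response, 0.0192 for glycolysis and 0.0118 for endothelial tip cell. It was 0.0215 for basement membrane and vascular matrix, 0.00495 for angiogenic signalling and 0.0219 for integrated stress and unfolded protein response. For pan-endothelial fry gave 0.0558.

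Directions turned for some genes that had not passed. Without the Hox-expressing libraries the log2 values were 0.064 for Ackr1, -0.097 for Aldh1a2, 0.00229 for Slc4a2, 0.11 for Pla2g6, 0.018 for Tm7sf2, -0.083 for Pmel, 0.14 for Kdm6a and 0.25 for Kdm5c. Without single libraries they ran from -0.27 to 0.046 for Eif2s3x and from -0.21 to 0.099 for Kdm5c, turning without wild-type replicate 2. Both genes are on the sex-linked list, and wild-type replicate 2 is the 1 female library, on which the sex term also rests. With the sex term Eif2s3x was 0.046 and Kdm5c 0.098, and Kdm5c was 0.000887 with the Krt5 covariate and 0.025 with the beta-globin term. Some lists that had not passed were called in opposite directions. Meningeal fibroblast was lower without the Hox-expressing libraries (adjusted p = 2.7e-04) and higher without wild-type replicate 1 (7.7e-04). Intermediate progenitor was higher (0.00700) and lower (0.0140) in those fits. Cell cycle was higher without the Hox-expressing libraries (0.0235), and lower without knockout replicate 1 (0.0392), knockout replicate 2 (0.00273) or wild-type replicate 1 (7.7e-04). Choroid plexus ran from adjusted p = 0.00114 to 0.928 without single libraries, higher without knockout replicate 1 (0.00114) or wild-type replicate 2 (0.831) and lower without the others, including knockout replicate 3 (0.0226).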

Other observations

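The tests of endothelial share, epidermal tissue, caudal tissue, embryo maturity and genotype were chosen after the results they bear on were seen, as were the reading of skin and caudal tissue apart and the requirement that the calls stay. Stress genes also rose in the knockout brains. Of 39 integrated stress and unfolded protein response genes, 8 rose and 0 fell, and 16 were higher and 0 lower when adjusted over the list alone (camera in limma, adjusted p = 1.3e-15; adjusted p = 0.211 with an estimated correlation). The 8 became 3 without knockout replicate 1, 4 without knockout replicate 3, 2 without wild-type replicate 2, 3 without wild-type replicate 3, 2 with the sex term and 0 without wild-type replicates 2 and 3. They included Trib3 at 3.26 (SE 0.316), Atf3 at 1.84 (SE 0.217) and Eif4ebp1 at 1.32 (SE 0.178) on the log2 scale. This stress list shared 3 members with the hypoxia list, Stc2 among them. Of 26 immediate early genes 2 rose, Egr1 and Atf3, which is also on the stress list (camera, adjusted p = 2.2e-06; adjusted p = 0.227 with an estimated correlation). Of 25 p53 response genes 2 rose, Eda2r and Sesn2, which is also on the stress list (camera, adjusted p = 2.3e-05; adjusted p = 0.226 with an estimated correlation). Both lists had 0 genes higher without knockout replicate 3, without wild-type replicate 2, with the sex term and without wild-type replicates 2 and 3. Without knockout replicate 1 or wild-type replicate 3 the immediate early list had 1 and the p53 list 0, without knockout replicate 2 the p53 list had 1, and without wild-type replicate 1 they had 3 and 5.

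The midbrain, cerebellum and hindbrain list was lower in camera with 0 of 22 members past the threshold in edgeR (adjusted p = 4.4e-05; adjusted p = 0.414 with an estimated correlation). Of the 22, 11 had an unadjusted p under 0.05 in edgeR, DESeq2 called 4 and limma-voom called 0. Its Hox members were high in wild-type replicates 2 and 3 and low in wild-type replicate 1. As mean log2 CPM relative to each gene's mean, the list was at 1.38 and 0.942 in wild-type replicates 2 and 3. It was at -0.174 in wild-type replicate 1, and at -0.774, -1.08 and -0.296 in knockout replicates 1, 2 and 3. The list was thus highest in wild-type replicates 2 and 3, and wild-type replicate 1 also lay above each knockout library.

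The 129 calls were compared with other groupings. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 129 genes and the highest of the others 1824, so 2 of the 10, the real one included, called at least 129. The split with 1824 sets knockout replicates 1 and 3 and wild-type replicate 1 against the rest, which points to a structure of the samples other than genotype.

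Pan-endothelial genes moved apart. If the knockout brains held only a larger share of endothelial cells, markers confined to these cells would rise about alike. Of the 30 members, 17 had a 95% interval that excluded the list median of 0.15 on the log2 scale, 11 above and 6 below. Not every member is confined to endothelium, such as Tal1, which is also on the erythroid list. The count therefore does not settle whether the endothelial share changed. Library scaling was not tested: the other scalings changed the number of members past the threshold by at most 1 per direction, but they shifted all genes by a median of at most 0.0020 on the log2 scale. A change of state within endothelial cells, alone or with a change in their number, may remain as a hypothesis and was not tested.

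Some libraries carried epidermal or Hox transcripts: of the 20 epidermal markers first listed, 11 had appeared in earlier output, and a first run on all 20 gave 90%, which met the 90% set. The other 9 alone gave 77.8% higher in both knockout replicate 1 and wild-type replicate 1 than in the comparison libraries, which leave out knockout replicate 3, so attached skin may be a source but was not settled. Of 9 Hox genes not seen before, 44.4% were higher in both wild-type replicates 2 and 3 than in the rest (50% of 10 in a first run). The 44.4% is under the 50% set against more caudal tissue. The 9 summed to 21.3 CPM in wild-type replicate 2 but to 0.778 in wild-type replicate 3. The latter is below knockout replicate 1 (3.22) and wild-type replicate 1 (2.34). It was decided after seeing this that levels so near the floor exclude nothing. The 9 also leave out Hox members of the fixed lists, such as Hoxa3, Hoxa4 and Hoxc4. Those were at 10.4, 9.67 and 15.6 CPM in wild-type replicate 2 and at 4.81, 2.75 and 4.15 CPM in wild-type replicate 3. In the other libraries they were at most 0.654 CPM. Skin as the source of the knockout calls was not settled. Without knockout replicate 1 and wild-type replicate 1, 122 of the 129 genes still passed. The median share of the log2 fold change was then 99.9%, but genes called with no overlap already lay apart in the libraries kept. The 9 epidermal genes still summed to 181 and 197 CPM in knockout replicates 2 and 3. They summed to 151 and 166 CPM in wild-type replicates 2 and 3. Krt5 was at 3.73 and 20.4 CPM in those knockout libraries and at 3.54 and 0.339 CPM in those wild-type libraries. In the libraries left out it was at 105 and 79.9 CPM. The sum of the 9 genes is thus not a measure of skin alone. That fit removes most of the Krt5 signal but leaves some in knockout replicate 3. With the Krt5 covariate 121 of the 129 genes still passed. These genes were selected as lying apart between the groups, so neither fit settles skin as their source. Caudal tissue as their source stays open: against wild-type replicate 1 alone the median share was 98.7%, above the 80% set beforehand, but that bound was wrong, because genes called with no overlap already lay apart in that library, and in this fit with 1 wild-type library the median SE went from 0.125 to 0.189 and 19 of the 129 passed.

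The beta-globin sets hold both genotypes, with 2 libraries in the set that holds most of the other group, so genotype alone does not set them. An earlier test of embryo maturity asked whether the called genes kept their direction within both sets; it was void, because groups that do not overlap fix that outcome, and it was replaced. With a term for the sets, 122 of the 129 genes still passed, so most calls did not rest on the sets as cut. The term leaves differences within a set. Adult beta-globins were at 2239 and 2245 CPM in knockout replicates 1 and 3 against 1608 in wild-type replicate 1. In the other set they were at 920 CPM in knockout replicate 2 against 605 and 615 in wild-type replicates 2 and 3. The genes had also been selected as lying apart between the groups, so maturity as a source of the calls was not settled. The labels give 1 stage for all embryos, so differences in maturity among them may remain and cannot be measured here.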
